A study of Homo sapiens with 16 samples.

How the data were processed

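Binding of serum response factor (SRF) was measured by chromatin immunoprecipitation and sequencing in HEL-iMKL1 cells. Of the 16 samples, 8 were SRF precipitates and 8 were inputs. The 4 groups of SRF precipitates, with 2 replicates each, were untreated cells, cells given doxycycline (Dox) to overexpress MKL1, cells given TPA, and cells given both. In what follows, MKL1 overexpression stands for treatment with Dox. MKL1 was not measured in these samples, and none were Dox-treated cells without the inducible MKL1. An effect of Dox itself therefore cannot be told apart from that of MKL1. Groups and replicate numbers came from the sample labels. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The files held 1 peak list for each SRF precipitate, called per library and not on pooled replicates. The input samples had no file and were not analysed here. The control that each list was called against was not given in the sources used here.

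Bowtie 1.1.2, MACS2 2.1.0.20150420, DiffBind 2.0.7 and DESeq2 were named, with the genome build hg19, per the submitters' processing notes. Their settings, the filters and the use of duplicate reads were not given in the sources used here. In each deposited list, every peak carried a fold enrichment, a ratio of tags at the summit to the local background. The deposited lists also gave the −log10 of the p-value and of the q-value for every peak. The deposited score was 10 times the −log10 q cut to a whole number, which held for every peak of the 8 lists. The lowest −log10 q of a list lay between 1.32 and 1.56, so the lists held peaks at a q of up to 0.05. All peaks lay on chromosomes 1 to 22, X and Y, and no list repeated an interval. Fold enrichments, p-values and q-values of separately called lists were used to describe, rank or filter peaks within a list and were not tested between lists. Fold enrichments of several lists given for a region describe each list. Tag counts recovered from the fold and the p-value were compared between groups, as described below.

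Peaks of the 8 lists that overlapped by at least 1 bp were merged into regions, and each library was scored for holding a peak in each region. A region was called gained in a comparison when both libraries of the first group held it and neither library of the second did, and lost in the reverse case. A region was kept when all 4 libraries held it. Groups of 2 against 2 libraries cannot give an exact p below 0.333, so gained and lost regions carry no test, and the count under the other 2 ways to split the 4 libraries is given instead. Peak numbers were compared on the log2 scale with 2-sided exact permutation tests, with the label permuted within the states of the other treatment. These tests had 36 arrangements and a smallest p of 0.0556. For the difference of the TPA effects, the Dox label was permuted within TPA states. The reference of that test is no effect of Dox in either TPA state, so its p also depends on any Dox effect common to both. Overlap of replicates was measured by the Jaccard index, the regions shared by 2 libraries divided by the regions of either, and tested 1-sided over all ways to pair the 8 libraries. A peak's rank is its place by −log10 p within its list, in percent from the top.

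The named regions were chosen by a rule set before the data were examined. For each comparison the rule took the 10 gained and 5 lost regions with the best mean rank in the libraries that held them, and, for the shared set, the 10 best-ranked regions of all 8 libraries. Coordinates are those of the lists, in hg19, counted from 1. A genome sequence or gene annotation of that build was not used here. Genes, promoters and CArG boxes at these regions, and lists of SRF target genes, were therefore not analysed here.

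Sequencing depth was recovered from the lists. MACS2 computes the fold from the scaled tag count plus 1 and the background plus 1, and the p-value from a Poisson tail of the same numbers. From both, the genome background, the scale of a tag and the whole tags under each summit were solved. A whole tag count fitted the pair of values, within 0.01 on the −log10 scale, for at least 99.477% of the peaks of every list. Totals per library assume the effective genome size of 2700000000 bp that MACS2 uses for human by default, and this factor cancels in ratios between libraries. On 3 simulated lists, at least 99.967% of peaks returned the exact tag count. Those lists were made with the same formulas and had most peaks at the genome background. In the real lists 16.6% to 33.3% of peaks matched that background. The simulation is thus easier than the data and does not check the formulas. The recovered tags were also compared between groups at the 869 regions that all 8 libraries held and that were solved in each. For that, log2 tags per 1000000 recovered tags (tags per M) with a pseudocount of 1 tag were centred on each library's median and fitted with limma, with Benjamini-Hochberg adjustment over regions. This comparison was added after the lists had been seen. In a simulation of 869 regions for Dox+TPA against TPA, with 100 regions changed by 3-fold, 95% of the changed regions and 1 unchanged region were called. Its libraries had the same mean at every unchanged region and a fixed dispersion. It therefore does not measure false calls among libraries that differ in depth, enrichment or background. On simulated lists of 6000 regions, merging returned all 400 gained regions of Dox+TPA against TPA and all 100 lost regions of TPA against untreated cells. The simulated sites lay far apart, with the peaks of a site close together. This checks the counting and not how merging acts on close or shifted peaks.

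The alternatives set before the data were examined were a −log10 q of at least 5, lists cut to the length of the shortest list (1568 peaks, taken by −log10 p), a reciprocal overlap of 50%, summits within 100 bp, all contigs, merged peaks within a list, the replicate number as a block, permutation over all 70 arrangements, and leaving out each library in turn. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.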

Results

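SRF, a transcription factor of growth-responsive and cytoskeletal genes, was mapped in HEL-iMKL1 cells, a human erythroleukaemia line with doxycycline-inducible MKL1. MKL1 is a coactivator of SRF, and TPA is a phorbol ester that activates protein kinase C and is used to drive HEL cells toward megakaryocytes. Cells were left untreated, given 10 ng/ml Dox, given 15 nM TPA, or given both, each for 24 h. The 4 groups let the effect of Dox, given to overexpress MKL1, on SRF binding be compared without and with TPA. The 8 lists held 31999 peaks, which merged into 11205 regions with a median width of 296 bp. Recovered depth, in units of 1000000 tags (M), was 16.6 and 21.1 M in the untreated libraries, 12.9 and 29.4 M in the Dox libraries, 15.0 and 21.3 M in the TPA libraries, and 17.1 and 16.4 M in the Dox+TPA libraries. A set of 892 regions was held by all 8 libraries, and 4658 regions (41.6%) were held by a single library, which was Dox+TPA replicate 1 for 3066 of them.

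Some SRF sites ranked near the top of the lists of all 4 groups. The shared sites named here were chosen by their mean rank over the 8 libraries, so their high ranks follow from that choice. The best-ranked region of all 8 libraries was chromosome 5, 137800162 to 137801309, with a mean rank within the top 0.0271% of the lists. Its fold enrichment, the authors' value, lay between 71.2 and 109.4 in the 8 libraries. It was followed by chromosome 17, 43394270 to 43395111, chromosome 7, 5570071 to 5570684, and chromosome 19, 46220277 to 46221174. All 10 of the best-ranked shared regions had a mean rank within the top 0.363%. On average, replicates of a group shared more regions than libraries of different groups, though not in every group. The Jaccard index was 0.570 for the untreated, 0.528 for the Dox, 0.513 for the TPA and 0.500 for the Dox+TPA replicates, with a mean of 0.528. The 24 pairs of libraries from different groups had a mean of 0.353 and a range of 0.141 to 0.560, and the 4 pairs of untreated with Dox libraries had a mean of 0.523, above the TPA and Dox+TPA replicates. No other pairing of the 8 libraries reached the mean of the real one (exact permutation p = 0.0095, the smallest the pairings can give), and the next reached 0.519. With lists of equal length the mean was 0.646 within groups and 0.492 between groups (exact permutation p = 0.0095). In those lists the replicates overlapped at 0.673 (untreated), 0.689 (Dox), 0.528 (TPA) and 0.695 (Dox+TPA). Untreated and Dox libraries overlapped at a mean of 0.617, untreated and TPA libraries at 0.467, Dox and Dox+TPA libraries at 0.505, and TPA and Dox+TPA libraries at 0.465.

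**Figure D1:**
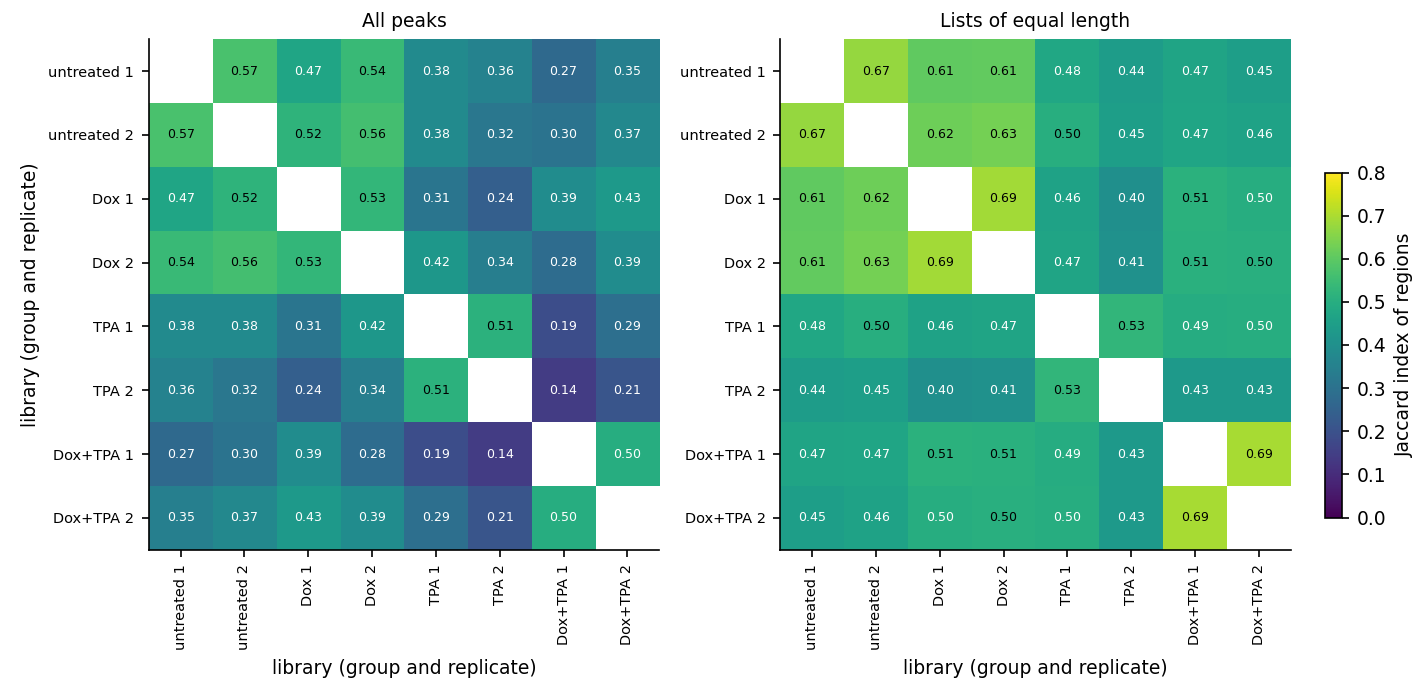
Jaccard index of regions for each pair of the 8 SRF libraries (both axes: group and replicate), with all peaks on the left and with each list cut to its best 1568 peaks on the right. The 4 same-group pairs average 0.528 and 0.646, above the averages of 0.353 and 0.492 for pairs of different groups.

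SRF peaks were most numerous after the combined treatment and least numerous after TPA alone. The untreated libraries had 3206 and 3444 peaks (mean 3325 ± 168, SD, n = 2), and the Dox libraries 4674 and 2799 (3736.5 ± 1326, SD, n = 2). The TPA libraries had 1794 and 1568 peaks (1681 ± 160, SD, n = 2), and the Dox+TPA libraries 9073 and 5441 (7257 ± 2568, SD, n = 2). Averaged over both TPA states, the log2 ratio of peak numbers with to without MKL1 overexpression was 1.09, a ratio of 2.14 (exact permutation p = 0.167). The corresponding log2 ratio for TPA was −0.01 (exact permutation p = 1). The TPA effect differed in sign between the backgrounds, with a log2 ratio of −0.99 in cells without Dox and 0.96 in cells with Dox. The difference of these effects was 1.94 (exact permutation p = 0.222, Dox label permuted within TPA states). It did not pass the threshold in a test whose smallest p is 0.0556. Both Dox+TPA libraries had more peaks than every library of the other groups, and both TPA libraries had fewer.

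**Figure D2:**
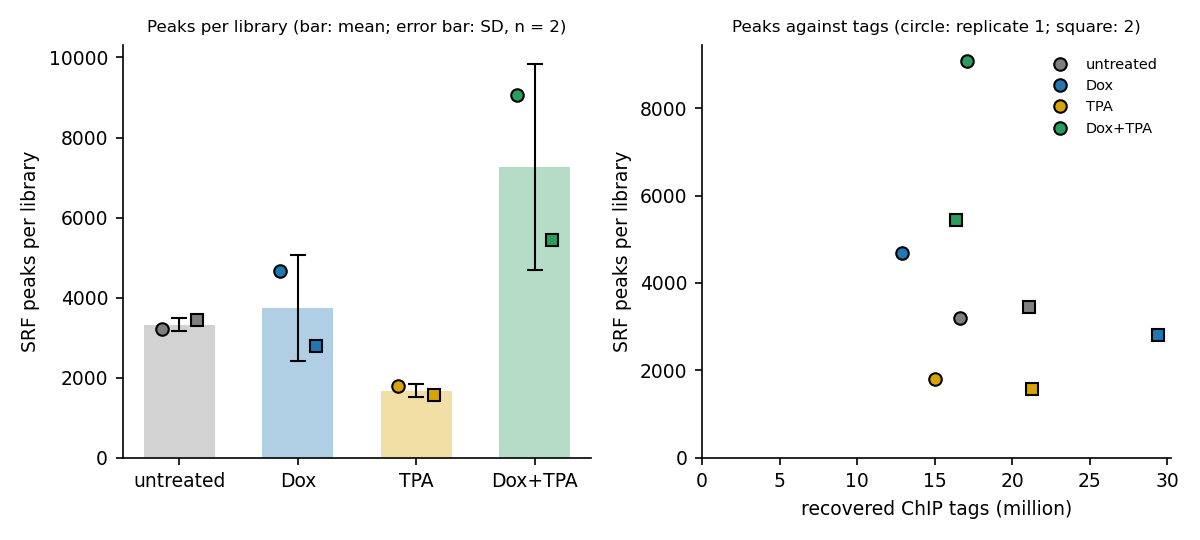
Left, SRF peaks per library (points), with the mean of each group (bar) and its SD (error bar, n = 2). Right, SRF peaks of each library against its recovered tags in M. The TPA libraries, with 15.0 and 21.3 M tags, had 1794 and 1568 peaks, and the Dox+TPA libraries, with 17.1 and 16.4 M, had 9073 and 5441.

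MKL1 overexpression without TPA left most SRF sites in place. Of the 2406 regions held by both untreated libraries, 1915 (79.6%) were kept in both Dox libraries, 292 regions were gained and 146 were lost. The best-ranked gained region was chromosome 1, 183404533 to 183405073, with fold enrichments of 20.3 and 12.7 in the Dox libraries. The next were chromosome 11, 130767623 to 130768140, with 16.7 and 13.9, and chromosome 8, 111622552 to 111622993, with 23.4 and 9.0. Of the 10 named gained regions, 9 were also held by both Dox+TPA libraries and 0 by a TPA library. Of all 292, 188 (64.4%) were held by both Dox+TPA libraries, against 2169 (84.2%) of all 2577 regions of Dox cells. No TPA library held 263 (90.1%) of the 292. The TPA lists were the shortest, with 1794 and 1568 peaks, and the share of all Dox regions absent from them was not computed. The best-ranked lost region was chromosome 15, 45875938 to 45876311, with 11.5 and 17.6 in the untreated libraries. The other splits of these 4 libraries gave up to 305 regions, so with all peaks the gained count did not exceed the spread between replicates. With lists of equal length 121 regions were gained and 101 lost, 222 in all, where the other splits gave at most 79 in all. Without untreated replicate 2 the counts were 531 gained and 622 lost, 1603 were gained without Dox replicate 2, and 581 and 462 were lost without untreated replicate 1 and Dox replicate 1.

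TPA alone was accompanied by the loss of many SRF peaks and the gain of few. Of the 2406 regions of untreated cells, 977 (40.6%) were kept and 963 were held by neither TPA library, while 80 were gained. The best-ranked lost region was chromosome 6, 841557 to 842031, with fold enrichments of 23.9 and 27.1 in the untreated and 20.6 and 15.3 in the Dox libraries. Other strong losses were chromosome 9, 14433029 to 14433555, and chromosome 14, 66893982 to 66894401. All 5 named lost regions were held by both Dox and both Dox+TPA libraries. Of all 963 lost regions 602 (62.5%) were held by both Dox libraries, against 1915 (79.6%) of all 2406 regions of untreated cells. The best-ranked gained region was chromosome 17, 54827198 to 54827914, with 25.4 and 19.6 in the TPA and 41.5 and 26.6 in the Dox+TPA libraries. It was followed by chromosome 5, 98950560 to 98950983, with 28.3 and 16.3, and chromosome 1, 59193004 to 59193571, with 14.3 and 13.0. All 10 named gained regions were also held by both Dox+TPA libraries, as were 64 of all 80 (80%). Of all 1135 regions of TPA cells, 1055 (93.0%) were held by both Dox+TPA libraries. The other splits of the 4 libraries gave up to 117 regions, below the lost count and above the gained count. With lists of equal length 181 regions were gained and 253 lost. Without untreated replicate 1 the lost count was 1821, and without untreated replicate 2 it was 1565, with 134 gained. The gained count was 215 without TPA replicate 1 and 277 without TPA replicate 2.

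In cells given TPA, MKL1 overexpression came with 3057 gained and 20 lost SRF regions. Of the 1135 regions of TPA cells, 1055 (93.0%) were kept. The best-ranked gained region was chromosome 11, 130767623 to 130768140, with fold enrichments of 43.1 and 28.2 in the Dox+TPA and 16.7 and 13.9 in the Dox libraries, and no peak in the untreated or TPA libraries. The next was chromosome 12, 124426027 to 124426568, with 51.5 and 28.7, held also by both untreated libraries with 7.8 and 4.4. It was followed by chromosome 6, 125335450 to 125335972, with 40.7 and 33.4, and chromosome 2, 10950490 to 10951149, with 42.2 and 30. All 10 named gained regions were held by both Dox libraries, and 7 by both untreated libraries. The whole set differed from these top-ranked regions: of the 3057, 806 (26.4%) were held by both Dox libraries, 618 (20.2%) by both untreated libraries, and 1414 (46.3%) by no untreated or Dox library. The best-ranked of the lost regions was chromosome 21, 28941602 to 28941953, with 8.0 and 14.7 in the TPA libraries. Of the 963 regions lost with TPA alone, 618 (64.2%) were held by both Dox+TPA libraries, 237 by 1 of them and 108 by neither. Of all 2406 regions of untreated cells, 1954 (81.2%) were held by both Dox+TPA libraries. The other splits of the 4 libraries gave up to 57 regions. With lists of equal length 262 regions were gained and 188 lost. Without Dox+TPA replicate 2 the gained count was 7126, and the lost count was 75 without Dox+TPA replicate 1, 232 without TPA replicate 1 and 51 without TPA replicate 2.

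**Figure D3:**
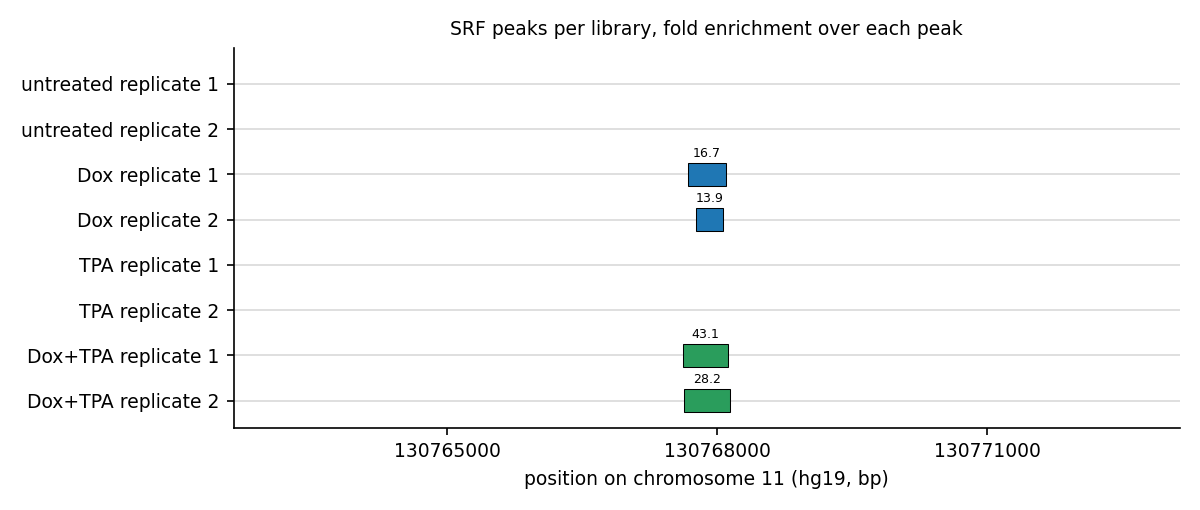
SRF peaks of each library around chromosome 11, 130767623 to 130768140 (x axis: hg19 position in bp; rows: libraries; boxes: peaks; numbers: the authors' fold enrichment). Both Dox libraries (16.7 and 13.9) and both Dox+TPA libraries (43.1 and 28.2) held a peak, and the untreated and TPA libraries held no peak in this window.

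In cells overexpressing MKL1, TPA came with 1758 gained and 101 lost SRF regions. Of the 2577 regions of Dox cells, 2169 (84.2%) were kept. The best-ranked gained region was chromosome 8, 126568476 to 126568970, with fold enrichments of 42.8 and 31.9 in the Dox+TPA and 12.0 and 8.1 in the TPA libraries. Chromosome 4, 180146752 to 180147352, had 38.3 and 35.7, and chromosome 2, 74779169 to 74779742, had 46.2 and 33.2 in the Dox+TPA libraries. Of the 10 named gained regions, 9 were held by both TPA libraries and 0 by both untreated libraries. Of all 1758, only 56 (3.19%) were held by both TPA libraries, and 1414 (80.4%) by no TPA or untreated library. The best-ranked lost regions were chromosome 21, 40735270 to 40735716, with 17 and 11.3 in the Dox libraries, and chromosome 2, 158903605 to 158903995, with 14.7 and 11.6. All 5 named lost regions were also held by both untreated libraries and by neither TPA library, while of all 101, 31 were held by both untreated libraries and 91 by neither TPA library. The other splits gave up to 584 regions, and lists of equal length gave 279 gained and 229 lost regions. The gained count was 5057 without Dox+TPA replicate 2, and the lost count was 751 without Dox replicate 2 and 390 without Dox+TPA replicate 1.

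Against untreated cells, the combined treatment came with 2225 gained and 130 lost regions, and 1954 of the 2406 regions of untreated cells (81.2%) were kept. The best-ranked gained region was chromosome 14, 89734034 to 89734520, with fold enrichments of 56.6 and 49.0 in the Dox+TPA and 16.5 and 10.8 in the TPA libraries. Its mean rank lay within the top 1.39% of the Dox+TPA lists. Chromosome 21, 37584220 to 37584862, had 40.1 and 24.0, and chromosome 1, 86044064 to 86044623, had 46.9 and 28.7. Of the 10 named gained regions, 8 were held by both TPA libraries and 4 by both Dox libraries. Of all 2225, 64 (2.88%) were held by both TPA libraries, 188 (8.45%) by both Dox libraries and 1414 (63.6%) by no TPA or Dox library. The best-ranked lost region was chromosome 3, 196244728 to 196245061, with 17.5 and 9.6 in the untreated libraries. The other splits gave up to 237 regions, and lists of equal length gave 332 gained and 278 lost regions. The gained count was 5770 without Dox+TPA replicate 2, and the lost count was 480, 526 and 435 without untreated replicate 1, untreated replicate 2 and Dox+TPA replicate 1.

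**Figure D4:**
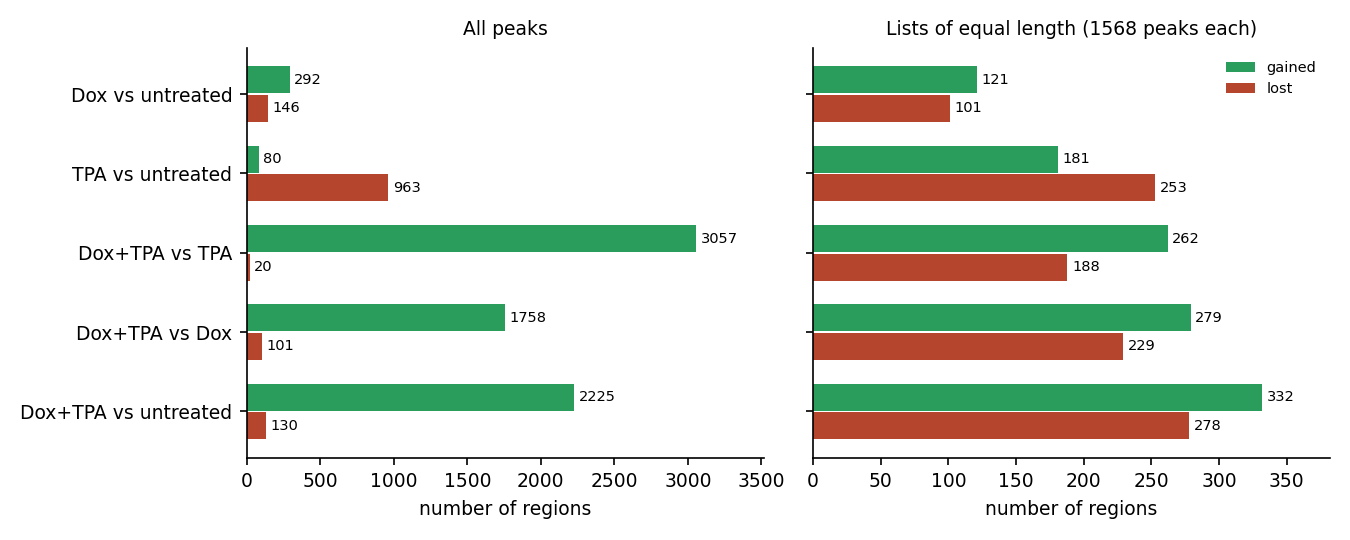
Number of regions gained (green) and lost (red) in each comparison, with all peaks on the left and with lists cut to 1568 peaks on the right. With all peaks, Dox+TPA against TPA had 3057 gained and 20 lost regions, and with lists of equal length 262 and 188.

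SRF peaks seen under the combined treatment alone numbered 1414 regions, held by both Dox+TPA libraries and by none of the other 6. The best-ranked were chromosome 6, 29196582 to 29197015, with fold enrichments of 27.2 and 17.4, chromosome 3, 127472904 to 127473456, with 29.7 and 20.3, and chromosome 19, 3568644 to 3569086, with 26.8 and 21.4. The highest count for any of the other 27 pairs of libraries was 351, for Dox replicate 1 with Dox+TPA replicate 1. The Dox+TPA lists were the longest, with 9073 and 5441 peaks, which by itself favours this pair. The comparison of pairs therefore does not show that the regions are particular to the combined treatment. The untreated, Dox and TPA pairs alone held 41, 38 and 7 regions. With lists of equal length the count for Dox+TPA was 112, and the other pairs were not counted at that length. Without Dox+TPA replicate 2 the count with all peaks was 4480.

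The split by Dox, taken as MKL1 overexpression, parted the 8 libraries in 162 regions. All of these regions were held by the 4 Dox-treated libraries and by none of the other 4. They were led by chromosome 11, 130767623 to 130768140, chromosome 1, 183404533 to 183405073, chromosome 11, 86527327 to 86527820, and chromosome 17, 37024412 to 37024898. In the last, the fold enrichments were 18.4 and 10.1 in the Dox and 26.4 and 15.7 in the Dox+TPA libraries. Among the 35 splits of the 8 libraries into 4 and 4, no other parted as many regions, and the next parted 94. With lists of equal length 42 regions were parted by MKL1 overexpression, and the split by TPA parted 122. Without untreated replicate 2 the count was 274, and without Dox replicate 2 it was 521.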

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

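The tests of tag depth, of control depth and of correlation below were chosen after the peak numbers had been seen, and the tests of ranks and of lists of equal length were set before their results were seen, except for the limits that list length put on the ranks, which were worked out afterwards. The TPA effect on the number of SRF peaks had opposite signs in the 2 backgrounds: both TPA libraries lay below both untreated libraries, and both Dox+TPA libraries lay above both Dox libraries. The log2 difference of the effects was 1.94 and did not pass the exact permutation test (p = 0.222, smallest possible p 0.0556).

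The excess of regions in Dox+TPA over TPA, 3057 gained against 20 lost, did not follow depth. The mean of recovered tags in Dox+TPA libraries was 0.922 times that in TPA libraries, and that of recovered control tags 1.01 times. The control was not named in the sources used here, so these tags may come from an input or another control. Of the gained regions, 0.916% ranked above the median kept region. With the kept regions at their ranks, the length of the lists allowed at most 10.2%, below the 15.6% set as the bound against overall enrichment (2 times the highest share between replicates, 7.82%), so this share decides nothing, and how far overall enrichment raised the number of regions stays open. In lists of equal length, Dox+TPA and TPA were parted by 450 regions, 6.08 times the higher of the other splits (74). A single factor that kept the order of sites would not produce this. The order rests on p-values that also depend on the background, so the lists cannot show that a single factor would keep it. A treatment effect on single sites stays open, as does unequal background in weakly enriched lists, which was not tested.

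The smaller number of regions in TPA than in untreated cells had the same features. The untreated libraries had on average 1.04 times the recovered tags of the TPA libraries. Of the 963 lost regions, 1.66% ranked above the median kept region, where list length allowed at most 10.3%, so the share decides nothing here either. In lists of equal length, 434 regions parted the groups, 4.38 times the higher of the other splits (99). A single factor that kept the order of sites would not produce this, but whether the order was kept was not tested here either. The TPA replicates also overlapped less in those lists (Jaccard index 0.528) than the untreated replicates (0.673). Whether overall enrichment differed through the precipitation or through SRF binding in the cells was not tested.

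Across the 8 libraries, the log2 number of peaks was correlated with the log2 median tags per M at regions held by all 8 (Pearson r = 0.869, exact permutation p = 0.00645, adjusted 0.0129 over 2 relations; Spearman rho = 0.905, exact permutation p = 0.00456). Without TPA replicate 2 and Dox+TPA replicate 1, the libraries farthest from the median, r was 0.648 (exact permutation p = 0.161) and rho 0.771 (exact permutation p = 0.103), so the sign stayed and the passing of the threshold rests on those libraries. The correlation with recovered tags was −0.295 (exact permutation p = 0.482; rho = −0.333, exact permutation p = 0.428), and −0.215 without Dox replicates 1 and 2. In these permutation tests the libraries were permuted freely, which treats replicates of a group as independent. The p-values therefore do not measure a relation across the 4 treatment groups. The median tags per M at the shared regions were 3.55 and 3.75 in the untreated, 5.26 and 2.72 in the Dox, 3.13 and 1.93 in the TPA, and 5.74 and 3.72 in the Dox+TPA libraries.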

How the results depend on the processing

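The results at regions of all 8 libraries, the count parted by TPA, the leave-one-out values of replicate overlap, and all their alternatives were chosen after seeing the data. The CArG share, the promoter share and the gene lists were not run, for want of a genome or annotation of the build in use. All contigs and merged peaks changed no value. A −log10 q of at least 5, a reciprocal overlap of 50% and summits within 100 bp left every count of regions within 1.5 times its main value and replicate overlap past its threshold, and the log2 effect of TPA on peak number, near 0 in any case, became 0.000797 at a −log10 q of at least 5. Permutation over all 70 arrangements gave p = 0.0857 for MKL1 overexpression.

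In lists of equal length, gained regions numbered 121 for Dox against untreated, 181 for TPA against untreated, 262 for Dox+TPA against TPA, 279 for Dox+TPA against Dox and 332 for Dox+TPA against untreated, and lost regions 101, 253, 188, 229 and 278. Regions of Dox+TPA alone numbered 112, those parted by MKL1 overexpression 42 and those parted by TPA 122. In replicate overlap the call did not change.

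Replicate differences in presence correlated at −0.0759 to 0.0152 between groups, so presence showed no pairing by replicate number. Pairing is not excluded by this. Recovered control tags were higher in replicate 2 of every group: 12.9, 15.1, 15.3 and 14.4 M in untreated, Dox, TPA and Dox+TPA. Replicate 1 had 11.1, 7.2, 9.5 and 10.6 M in that order. With the replicate block the exact p for peak number was 0.25 for MKL1 overexpression (log2 1.09), 1 for TPA and 0.5, the smallest that test can give, for the difference of the effects. At regions of all 8 libraries the block gave 23 called regions for Dox against untreated and 64 for the difference of the TPA effect, against 8 and 32 without it. It moved no other total by over 1.5 times, but all 6 totals were higher with it.

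Leaving out a library moved the TPA effect on peak number between −0.20 (without Dox replicate 2) and 0.17 (without Dox replicate 1). With 18 arrangements left, no p for peak number could fall below 0.0556, so these fits could not pass the threshold. Gained and lost regions could only rise, since fewer libraries had to meet the rule. The ranges were 401 to 1603 gained and 175 to 622 lost for Dox against untreated, 104 to 277 and 1090 to 1821 for TPA against untreated, 3212 to 7126 and 25 to 232 for Dox+TPA against TPA, 1863 to 5057 and 119 to 751 for Dox+TPA against Dox, and 2455 to 5770 and 147 to 526 for Dox+TPA against untreated. Regions of Dox+TPA alone ranged from 1444 to 4480, those parted by MKL1 overexpression from 165 to 521 and those parted by TPA from 73 to 170.

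At regions of all 8 libraries, limma with a library left out assumes that the lone sample varies like the other groups. The called regions then ranged from 0 to 30 for Dox against untreated, 49 to 183 for TPA against untreated, 99 to 232 for Dox+TPA against TPA, 40 to 246 for Dox+TPA against Dox, 151 to 404 for Dox+TPA against untreated (333 in the main fit) and 0 to 70 for the difference of the TPA effect. On tags per M the counts were 0, 1, 98, 5, 22 and 0 in that order, with 4, 134, 308, 67, 111 and 72 regions at an unadjusted p under 0.05. Cyclic loess gave 5 for Dox against untreated, 210 for Dox+TPA against untreated (118 higher and 92 lower, against 133 and 200) and 20 for the difference, and left the other totals within 1.5 times. The lower counts moved further, from 159 to 100 for Dox+TPA against TPA and from 77 to 49 for Dox+TPA against Dox. Of the 149, 250 and 161 regions called for TPA against untreated, Dox+TPA against TPA and Dox+TPA against Dox, 101, 171 and 129 were also called after loess in the same direction. The cause of these shifts was not tested. Depth limits the weak regions: at 12.9 to 29.4 M tags, a region missing from a list is not shown to be unbound.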

Other observations

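The tests in this part were chosen after the lists had been seen, except the count of splits for MKL1 overexpression with all peaks, and for the chromosome test and the test of Dox+TPA against TPA what would count was set before their results. At SRF sites that every library held, relative tag levels differed in the comparisons with a TPA-treated group, also where both groups had TPA. The numbers depended on the scaling and on single libraries. Whether TPA, Dox or unequal background caused this stays open. Among 869 such regions, limma on median-centred tags called 78 higher and 71 lower in TPA than in untreated cells. In Dox+TPA it called 91 higher and 159 lower against TPA (250 in all), and 84 higher and 77 lower against Dox. After cyclic loess these counts were 76 and 48, 103 and 100, and 93 and 49, so the balance of rises and falls depended on the scaling. On median-centred tags, Dox against untreated cells gave 4 higher and 4 lower. The best-supported rise with TPA was at chromosome 16, 73802566 to 73803174, with 1.39 ± 0.0807 tags per M in untreated, 2.40 ± 1.09 in Dox, 5.84 ± 3.15 in TPA and 8.78 ± 2.57 in Dox+TPA libraries (SD, n = 2 each). Its log2 ratio of TPA to untreated was 2.48 (SE 0.193, limma adjusted p = 1.8e-06), and that of Dox+TPA to Dox was 1.61 (limma adjusted p = 0.000196). Chromosome 12, 12037958 to 12038544, rose with TPA by a log2 ratio of 2.28 (SE 0.18, limma adjusted p = 1.8e-06), and chromosome 16, 57034422 to 57034990, by 2.11. The best-supported relative fall was at chromosome 1, 155817487 to 155818085, with 7.04 ± 0.835 tags per M in untreated and 1.64 ± 0.792 in TPA libraries, and it stood at 8.55 ± 4.75 in Dox and 8.14 ± 1.66 in Dox+TPA libraries. Chromosome 12, 124603843 to 124604295, had 1.86 ± 0.758 in Dox and 7.50 ± 2.23 in Dox+TPA libraries, a log2 ratio of 1.72 on median-centred tags. It had 1.74 ± 0.161 in untreated and 2.14 ± 0.562 in TPA libraries. These tags per M were not centred, and the median at shared regions was lower in TPA (mean 2.53) than in untreated libraries (mean 3.65). A relative rise with TPA alone is therefore not excluded at this region. These regions were named by their p-value, after their values had been seen.

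Part of the calls with TPA at shared sites recurred in a comparison of other libraries. TPA against untreated cells and Dox+TPA against Dox use no library in common. In both, 46 regions were higher, where 7.54 would be shared by independent lists, and 14 were lower, where 6.29 would be. Both sets of calls came from 1 fit with 1 variance per region, so a region of low variance can be called in both. The 2 sets are thus not independent, and the excess over the expected numbers is not a test. Opposite calls were made at 3 regions. Across the 869 regions, which are not independent replicates, the log2 ratios correlated at r = 0.469 (rho = 0.388), with the same sign at 64.1%. The ratios for Dox, in TPA-treated and other cells, correlated to a similar degree (r = 0.402, rho = 0.452, same sign at 67.9%), so the correlation is not particular to TPA. The shared calls for Dox were 4 higher (0.419 expected) and 1 lower (0.732 expected). Cyclic loess, which removes trends with site strength, also used all 8 libraries together. After it, 37 regions were higher in both TPA comparisons (8.13 expected), 13 were lower (2.71 expected) and r was 0.460. For Dox, 1 region was then higher in both (0.119 expected) and 0 were lower (0.46 expected), with r of 0.356. Without untreated replicates 1 and 2 in turn, TPA against untreated called 49 and 69 regions. Dox+TPA against TPA called 99 and 149 without Dox+TPA replicates 1 and 2, and Dox+TPA against Dox called 83, 49, 65 and 40 without Dox replicates 1 and 2 and Dox+TPA replicates 1 and 2, and 246 without either TPA library. On tags per M without centring, 1, 98 and 5 regions were called in these comparisons, with 0, 98 and 5 higher, and the median log2 ratio was −0.53, 0.81 and 0.20, so the changes are relative to the median site.

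The parting of the libraries by TPA depended on list length. With all peaks, MKL1 overexpression parted 162 regions and TPA parted 69 (44 held by the 4 TPA libraries alone, 25 by the others). In lists of equal length the order was the other way, with 122 regions parted by TPA (66 held by the TPA libraries alone and 56 by the others) and 42 by MKL1 overexpression. Of the 35 splits of the 8 libraries, 1 parted as many regions as TPA did in lists of equal length, namely TPA itself, and the highest other parted 42. With all peaks, 4 of the 35 splits parted as many as TPA. Only 3 of the splits keep replicates together, too few for a share under 0.05. The count for TPA with all peaks was 109 without Dox replicate 2, 157 without TPA replicate 2 and 170 without Dox+TPA replicate 1. Regions held by the 4 TPA libraries alone with all peaks were led by chromosome 1, 59193004 to 59193571, chromosome 15, 70560242 to 70560690, and chromosome 12, 71032635 to 71033069.

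MKL1 overexpression parted 162 regions with all peaks, and the order of the splits changed with list length. Of the 35 splits, 1 parted as many, the real one, and the highest other, with 94 regions, set the 4 longest lists against the 4 shortest, so part of the 162 may come from the length of the lists. In lists of equal length, 42 regions were parted (28 held by the Dox-treated libraries alone and 14 by the others), 2 of the 35 splits parted as many, and the highest other was the split by TPA, with 122. The 3 splits that keep replicates together are too few for a share under 0.05 here too. Without untreated replicate 2 the count was 274 and without Dox replicate 2 it was 521.

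Regions of Dox+TPA alone lay less often on the gene-rich chromosomes 17, 19 and 22 than regions of all 8 libraries, 143 of 1414 (10.1%) against 119 of 892 (13.3%), with an odds ratio of 0.731 (Fisher's exact p = 0.0184, 2-sided). Of all 11205 regions, 1183 (10.6%) lay there, so the regions of all 8 libraries stood apart more than those of Dox+TPA alone. Distances to genes were not analysed here.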
